A study of Mus musculus with 12 samples.

How the data were processed

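RNA from sorted basal cells of the mammary glands of adult virgin female C57BL/6J mice was hybridised to Illumina BeadChips and stained with Cy3, per the labels. There were 12 arrays on 2 beadchips, 4 per group, and each beadchip held 2 arrays of every group. Per the labels the sorts were about 95% pure, each pool came from 6 mice, all RNA had an integrity number of at least 8, and cultures were kept at 5% CO2 and 5% oxygen. The sources used here are the sample labels, the series' design text, the deposited tables and a table of probe annotation.

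The authors deposited a table of non-normalized linear intensity values per probe and array, which ranged from 79.3 to 71100 and showed no subtracted background. They also deposited a table of normalized log2 values, from 6.48 to 16.03 with a median of 7.32 in every array. The software and settings behind both are not given in the sources used here. The deposited log2 values lay within 0.018 of a quantile normalization of the log2 non-normalized values computed here, and the series matrix held the same values (greatest difference 0). No detection p-values or control probes were used here, so no probe was called as above background. Changes of genes near the array median can be understated. Values near the top of the scale, such as Krt14, can be compressed as well.

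Of 45280 probes, 34885 were paired with 1 gene by the annotation table, 18 with several and 10377 with none. Of the named probes 34807 had a gene number found in the RefSeq gene table of GRCm38.p6, through which 0 symbols changed. The brightest probe by mean over the 12 arrays stood for each gene, giving 19057 genes. Probes with several genes or none were left out of the named results. Where a gene's probes disagreed, this is said beside it.

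Groups come from the sample titles. Replicate numbers follow the order of collection given in the titles within each group, and the design text says that the groups of an experiment came from one pool, which is what pairs them. The day 7 samples were collected 7, 8, 11 and 8 days after the sort with the same number. As a check on the pairing, deviations from the group means were correlated between same-numbered arrays, across genes above the median by mean. The correlations were 0.245, 0.177, 0.0954 and 0.0491 between pre-culture and day 1, 0.0128, -0.053, -0.0147 and -0.0858 between pre-culture and day 7, and 0.184, 0.107, -0.161 and 0.0468 between day 1 and day 7. For pre-culture and day 1, each pre-culture array correlated less with day 1 arrays of other numbers (at most -0.0367, 0.0574, 0.057 and 0.0437). Every pre-culture array correlated more with a day 7 array of another number (0.0559, 0.0425, 0.0643 and 0.114). So did replicates 2 to 4 of day 1 with day 7 arrays (0.211, 0.268 and 0.28). The highest of several values is compared with a single one here, which favours another number. The pairing of day 7 therefore rests on the titles and the design text and not on the values, and the main test does not use it. Because 4 separate pools were used, p-values measure the spread between pools, although mice within a pool cannot be told apart.

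The main test was fitted to the deposited log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated two-sided tests) over all 12 arrays with group means and no block. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. A second count asked in addition for a change of at least 2-fold. All adjusted p-values of genes in the text come from this fit unless another setting is named. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 28 lists, and again with the correlation estimated from the data and with fry. Camera asks whether a list moved against the other genes. Fry asks whether its members moved, on balance, one way, and compares them with no other genes. The groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined, save the 1 alternative and the tests named in the closing section as chosen later.

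The 28 lists were the contractile, basal identity, luminal, milk protein, mitosis, DNA replication, p53 target and cell cycle inhibitor, immediate-early and heat shock, ribosome biogenesis and Myc target, fibroblast and feeder cell, endothelial, pericyte, immune, adipocyte, basement membrane, epidermal and wound keratinocyte, epithelial-mesenchymal transition, Wnt target, Wnt ligand and receptor, Notch, proposed mammary stem cell, hypoxia and glycolysis, cholesterol synthesis, interferon, NRF2 target, YAP and TEAD target, EGF ligand, and integrin and focal adhesion genes. Some share members: 8 of the 24 basal genes and 12 of the 22 proposed stem cell genes are also in another list. Named genes are the 10 largest rises and the 10 largest falls per comparison among called genes whose groups of 4 do not overlap, up to 4 members per list and comparison with the largest change, the 10 most extreme of the genes highest or lowest at day 1, and a fixed panel of Krt5, Krt14, Trp63, Acta2, Krt8, Krt18, Mki67, Cdkn1a, Axin2, Lgr5, Snai2, Sox9 and Col1a1. Mki67 had no named probe here. Of the panel, Cdkn1a stood at 13.61 before culture, 13.00 at day 1 and 12.89 at day 7, Snai2 at 12.72, 11.63 and 12.30, and Sox9 at 13.95, 12.97 and 13.03.

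On simulated data with known changes in 19057 genes, the fit recovered 68.7% of genes changed 1.5-fold, 97% of those changed 2-fold and 100% of those changed 4-fold for day 1 against pre-culture, with 13 false calls. For day 7 against pre-culture it recovered 70.1%, 94% and 100% with 11 false calls, and for day 7 against day 1 79.1%, 92.5% and 98.5% with 11 false calls. Of 28 lists the 1 shifted list was called and no other. The simulated genes varied independently, whereas the inter-gene correlation estimated from the data reached 0.49 in the interferon list. This check therefore does not cover lists whose members vary together.

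The alternatives were the replicate number as a block, the beadchip as a block and each beadchip alone, normexp background correction (offset 50) with quantile normalization, median centring without a quantile step, quantile normalization without background correction, the series matrix values, only genes above the median by mean, the mean of a gene's probes, every probe, trend and robust options, array weights, only the 2 groups compared, and each array left out in turn. Leaving out experiment 1 in all groups was added after the data were seen. Chance values for shared controls came from 50 simulations of unchanged groups and from 6 divisions of the shared arrays into sets of 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.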

Results

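RNA from basal cells of the mouse mammary gland was measured on 12 single-colour bead arrays (Illumina BeadChips stained with Cy3), 4 in each of 3 groups. One group was taken directly after cell sorting (pre-culture), and the others after 1 day and after 7 days of culture. Basal cells form the outer layer of the mammary ducts. Per the labels they are mainly contractile myoepithelial cells, and stem cells made up about 1 in 300 of them before culture, 1 in 30 at day 1 and 1 in 70 at day 7. The comparisons ask which molecular changes in culture accompany the rise in stem cell frequency. Each array measured all basal cells of a sample together, so its values reflect mainly the cells that were not stem cells. Each of 4 experiments pooled the glands of 6 mice and divided the sorted cells among the 3 groups. The pre-culture cells had been through an overnight enzyme digestion. The cultured cells had in addition met Matrigel, a keratinocyte medium, the Rho kinase inhibitor Y-27632 at 10 µM, irradiated 3T3 fibroblast feeder cells and 5% oxygen, and were sorted again to remove the feeders. A difference between culture and pre-culture therefore covers all of these together.

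The raw intensities reached 71100, and their median was 150.6 ± 2.92 in the pre-culture arrays, 167.1 ± 7.28 at day 1 and 162.9 ± 16.5 at day 7 (SD, n = 4 each). The upper quartile was further apart, at 260.8 ± 13.02, 365.9 ± 15.6 and 334.1 ± 49.5 (SD, n = 4 each). Within groups the arrays correlated at r = 0.988 to 0.991 before culture, 0.992 to 0.996 at day 1 and 0.979 to 0.994 at day 7, across genes, which are not independent replicates. The first principal component held 73.6% of the variance and separated the cultures from the pre-culture cells. The second held 16.8% and separated day 1 from the other groups. The number of arrays limits the precision of every value given here.

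**Figure D1:**
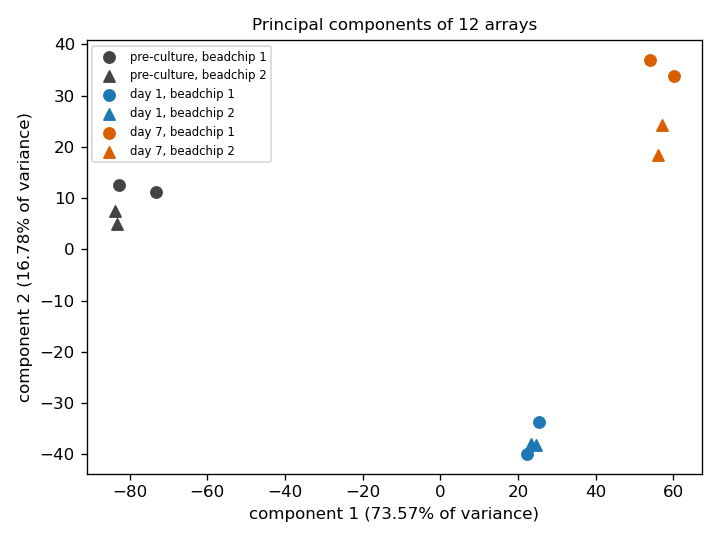
Scores of the 12 arrays on the first and second principal component of the normalized log2 values of 19057 genes, coloured by group, with circles for beadchip 1 and triangles for beadchip 2. The axes hold 73.6% and 16.8% of the variance, and the arrays of each group lie nearer each other than to other groups. On the second component the day 7 arrays of beadchip 1 (33.9 and 37.0) lie above those of beadchip 2 (18.5 and 24.2).

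After 1 day in culture, most measured genes of muscle-like contraction, of the early stress response, of hypoxia and of the interferon response were lower than in freshly sorted cells, while most genes of DNA replication, ribosome biogenesis and the NRF2 antioxidant response were higher. Of the 16 lists called, only the early stress and hypoxia lists stayed called with an estimated correlation (adjusted p = 0.0412 each), and contractile (0.149), interferon (0.16), replication (0.254), ribosome (0.106) and NRF2 genes (0.0663) did not. The largest rises were in Gsta2 (log2 fold change 5.96 ± 0.285 SE, adjusted p = 1.12e-09, n = 4 per group) and Gsta1 (5.95 ± 0.2998, adjusted p = 1.68e-09), which encode glutathione transferases that detoxify electrophiles. The cell cycle driver Ccnd1 rose by 4.92 ± 0.285 (adjusted p = 6.01e-09) and Epgn, a ligand of the EGF receptor, by 4.44 ± 0.192 (adjusted p = 4.84e-10). The largest fall was in Igfbp5, a secreted binding protein for insulin-like growth factors (-6.09 ± 0.135, adjusted p = 2.31e-12), followed by the endothelin gene Edn2 (-6.06 ± 0.277, adjusted p = 7.61e-10). Pdk4, a kinase that restrains glucose oxidation, fell (-5.39 ± 0.157, adjusted p = 1.84e-11), and the atrophy ubiquitin ligase Fbxo32 (-5.38 ± 0.162, adjusted p = 2.41e-11).

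In the limma fit, 7692 of 19057 genes differed between day 1 and pre-culture at an adjusted p under 0.05, 4270 higher and 3422 lower. Of these, 3257 changed at least 2-fold, 1733 upward and 1524 downward. With each array centred on its median and no quantile step, 70.3% of the called genes were higher at day 1, against 55.5% as normalized by the authors. Within beadchip 1 alone 6762 genes were called and within beadchip 2 alone 6744, and with the beadchip as a block 7806.

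Among 22 measured myoepithelial contractile genes, 17 fell at day 1, 0 rose and 5 were not called (18 fell when adjusted over the list alone). Camera gave adjusted p = 6.72e-10 for the list, and adjusted p = 0.149 with an estimated correlation. The intermediate filament gene Synm fell (-5.40 ± 0.135, adjusted p = 4.29e-12) and the actin-binding Pdlim3 (-5.04 ± 0.197, adjusted p = 2.04e-10). Acta2, the smooth muscle actin that marks these cells, stood at 15.69 before culture and 14.90 at day 1 and was not called with its brightest probe (-0.79 ± 0.390, adjusted p = 0.137, n = 4 per group). It was called with the mean of its 6 probes (-1.80, adjusted p = 0.000249), without replicate 1 of day 1 (-1.10, adjusted p = 0.0313) and without replicate 1 of day 7 (adjusted p = 0.0372).

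Of 26 immediate-early and heat shock genes, which respond within minutes to stress and dissociation, 21 fell and 1 rose (21 and 1 when adjusted over the list alone). This was one of 2 lists at day 1 whose call held with an estimated correlation (camera adjusted p = 8.15e-11, and 0.0412 with an estimated correlation). The stress transcription factor Atf3 fell (-4.85 ± 0.144, adjusted p = 2.21e-11) and the heat shock protein gene Hspa1a (-3.98 ± 0.194, adjusted p = 1.25e-09). The other was the hypoxia and glycolysis list, in which 21 of 25 genes fell and 1 rose (22 and 1 when adjusted over the list alone, camera adjusted p = 8.15e-11, and 0.0412 with an estimated correlation). The hypoxia-induced peptide hormone gene Adm fell (-4.62 ± 0.193, adjusted p = 3.64e-10) and the oxygen sensor Egln3 (-4.27 ± 0.222, adjusted p = 2.22e-09), although the labels give a lower than atmospheric oxygen level for the cultures. Of 22 interferon response genes 18 fell and 0 rose (the same counts adjusted over the list alone). The list test gave adjusted p = 6.72e-10, and adjusted p = 0.16 with an estimated correlation. Ifit3 fell (-4.98 ± 0.219, adjusted p = 5.44e-10) and Gbp2 (-4.18 ± 0.282, adjusted p = 2.49e-08).

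The 4 lists called higher at day 1 were those of DNA replication, ribosome biogenesis, NRF2 targets and cholesterol synthesis. Of 28 DNA replication genes 25 rose and 0 fell (25 and 0 adjusted over the list alone). As a list they had adjusted p = 1.3e-07, and adjusted p = 0.254 with an estimated correlation. The replicative helicase subunit Mcm5 rose by 3.13 ± 0.403 (adjusted p = 1.55e-05) and the flap endonuclease Fen1 by 2.49 ± 0.210 (adjusted p = 2.31e-07). Mitosis genes were not called with them as a list. Of 24 only Birc5 was called (1.14 ± 0.315, adjusted p = 0.00869, and adjusted p = 0.191 within beadchip 1), none was called when adjusted over the list alone, and camera gave adjusted p = 0.929. The mitotic kinase Cdk1 stood at 9.05 before culture and 10.00 at day 1 (adjusted p = 0.105), and was called in some other settings, such as with the replicate number as a block (adjusted p = 0.0496) and without replicate 1 of pre-culture (1.46, adjusted p = 0.00151), with a range of 2.72e-05 to 0.768 over the settings. The spindle gene Cdca8 (0.92 ± 0.425, adjusted p = 0.111) was likewise called with that block (0.00322), within beadchip 2 (0.00027), under median centring (0.0266), without replicate 1 of pre-culture (0.00475) and without experiment 1 (0.00076), and not within beadchip 1. Cenpa, lower by contrast (-0.93 ± 0.371, adjusted p = 0.0636), was called with that block (0.0419), with a range of 0.00263 to 0.955. Of 23 ribosome biogenesis and Myc target genes 19 rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 3.57e-08, adjusted p = 0.106 with an estimated correlation), among them the nucleolar proteins Nop56 (3.29 ± 0.173, adjusted p = 2.5e-09) and Bop1 (2.82 ± 0.111, adjusted p = 2.18e-10). Of 20 NRF2 targets 15 rose and 2 fell (15 and 2 adjusted over the list alone). Camera put the list at adjusted p = 4.84e-05, and adjusted p = 0.0663 with an estimated correlation. They include the cystine importer Slc7a11 (3.22 ± 0.247, adjusted p = 8.82e-08) and Gclm, a subunit of the enzyme that starts glutathione synthesis (2.09 ± 0.119, adjusted p = 5.1e-09). Of 17 cholesterol synthesis genes 9 rose and 1 fell (9 and 1 adjusted over the list alone). Camera gave the list adjusted p = 0.0123, and adjusted p = 0.345 with an estimated correlation. That call was lost among genes above the median by mean (0.0805).

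Genes of other cell types that a sort can carry along were also lower at day 1 than before culture. Of 25 fibroblast and feeder cell genes 21 fell and 2 rose (21 and 2 adjusted over the list alone). The list test gave adjusted p = 3.47e-07, and adjusted p = 0.149 with an estimated correlation. The matrix proteoglycan gene Dcn fell (-5.29 ± 0.225, adjusted p = 4.22e-10), while the collagen gene Col1a1, at 9.03 ± 0.871 before culture (SD, n = 4), fell (-1.19 ± 0.309, adjusted p = 0.00582). Of 22 immune cell genes 12 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 0.000767, adjusted p = 0.335 with an estimated correlation), among them the antigen presentation gene H2-Ab1 (-4.18 ± 0.191, adjusted p = 7.55e-10). Of 18 endothelial genes 10 fell and 0 rose (10 and 0 adjusted over the list alone, camera adjusted p = 0.00294, adjusted p = 0.136 with an estimated correlation), with a fall in Plvap (-1.67 ± 0.104, adjusted p = 1.17e-08). The endothelial call was lost among genes above the median by mean (adjusted p = 0.0525). Of 11 pericyte genes 4 fell and 0 rose (3 and 0 adjusted over the list alone). As a list they had adjusted p = 0.0412, and adjusted p = 0.145 with an estimated correlation. That call was lost without replicate 2 of day 1 (adjusted p = 0.0509), without replicate 4 of day 1 (adjusted p = 0.0508) and within beadchip 1 (adjusted p = 0.0604). Adipocyte genes (4 of 14 fell, 0 rose, 4 and 0 adjusted over the list alone) were not called as a list (adjusted p = 0.0932).

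Lists tied to lineage and signalling were mixed at day 1. A change confined to stem cells, about 1 in 30 of the cells at day 1 by the labels, could be missed by any list test. Proposed mammary stem cell genes, of interest in the group with the highest labelled stem cell frequency, were not called as a list (6 of 22 rose, 10 fell, adjusted p = 0.311). Neither were epidermal (9 of 27 rose, 6 fell, 0.318), Notch (7 of 22 rose, 4 fell, 0.915), Wnt target (2 of 15 rose, 7 fell, 0.176) or Wnt ligand and receptor genes (6 of 32 rose, 13 fell, 0.0992). Milk protein (1 of 16 rose, 7 fell, 0.085), p53 target (5 of 22 rose, 12 fell, 0.0787), EGF ligand (3 of 8 rose, 0 fell, 0.0932) and integrin genes (6 of 23 rose, 11 fell, 0.132) were not called either.

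The epithelial and matrix lists that were called at day 1 were lower. Of 18 basement membrane genes 13 fell and 0 rose (14 and 0 adjusted over the list alone, camera adjusted p = 7.62e-07, adjusted p = 0.106 with an estimated correlation), including the type IV collagen Col4a5 (-3.17 ± 0.141, adjusted p = 5.66e-10). Of 24 luminal epithelial genes 10 fell and 0 rose (10 and 0 adjusted over the list alone, camera adjusted p = 0.00117, adjusted p = 0.106 with an estimated correlation), and the tight junction gene Cldn4 fell (-5.04 ± 0.241, adjusted p = 1.11e-09). Epithelial-mesenchymal transition genes fell in 14 of 21 cases and rose in 2 (14 and 2 adjusted over the list alone). Camera put the list at adjusted p = 0.00253, and adjusted p = 0.254 with an estimated correlation. Of 20 YAP and TEAD target genes 9 fell and 4 rose (10 and 4 adjusted over the list alone, camera adjusted p = 0.0146, adjusted p = 0.335 with an estimated correlation, and 0.051 within beadchip 1). Basal identity genes went both ways, with 8 of 24 higher, 8 lower and 8 not called (8 and 8 adjusted over the list alone). That list was not called (adjusted p = 0.585), and its mean of -0.24 and median of 0.03 differed in sign. Krt5 (0.26 ± 0.171, adjusted p = 0.284) and the basal transcription factor Trp63 (-0.02 ± 0.108, adjusted p = 0.942) were not called. Krt14 was 0.19 higher (SE 0.0716, adjusted p = 0.0435), a call that ended without any of the pre-culture replicates 1, 2 and 4, the 4 day 1 arrays or the day 7 replicates 2 and 3 (differences of 0.17 to 0.20), and with the replicate number as a block (adjusted p = 0.0626). Under median centring the difference of Krt14 all but vanished (0.01324, adjusted p = 0.921). The call was also lost within beadchip 1 (0.0837) and beadchip 2 (0.523), with normexp correction (0.134), with trend and robust options (0.107), among genes above the median by mean (0.0621) and without experiment 1 (0.125).

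**Figure D2:**
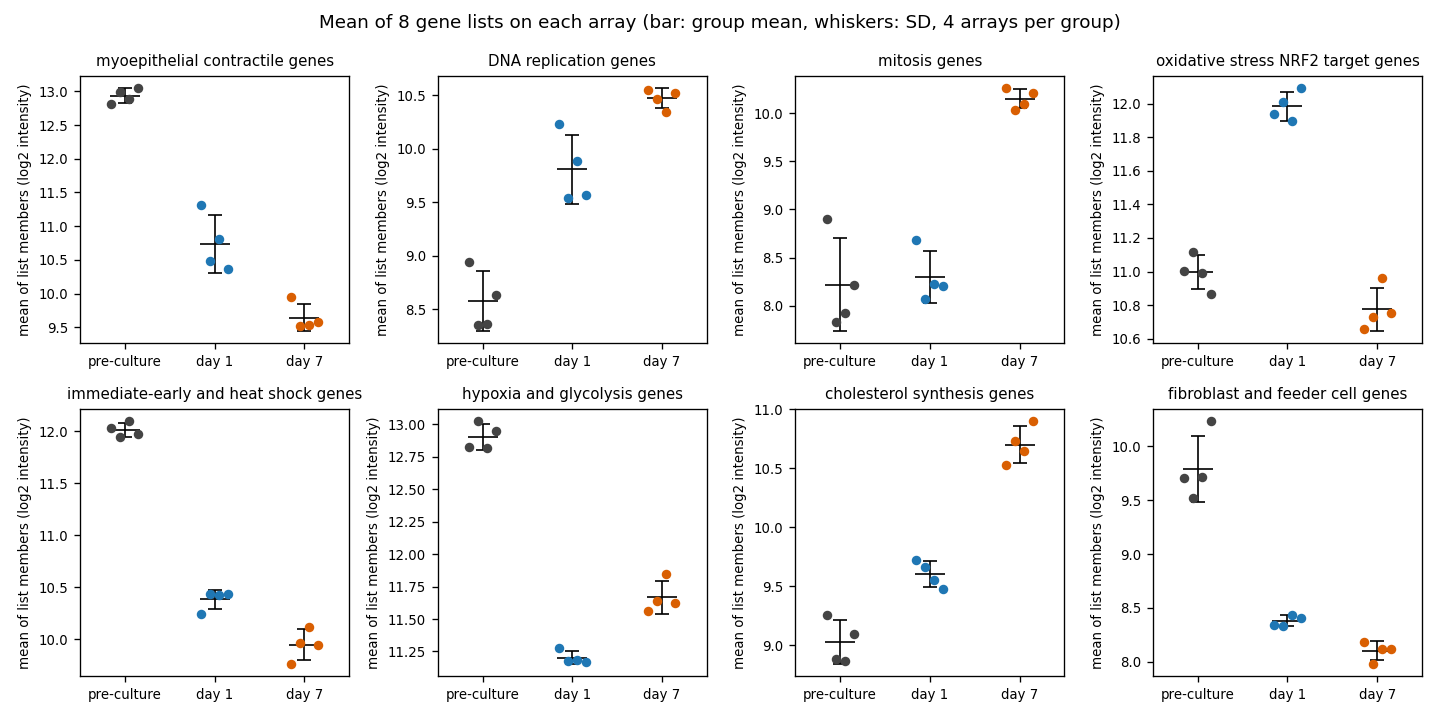
Mean log2 intensity of the members of 8 gene lists on each array, by group (points: arrays, bar: group mean, whiskers: SD, n = 4). Contractile genes changed by -2.20 at day 1 and by a further -1.09 at day 7, DNA replication genes were already 1.24 higher at day 1, and mitosis genes were 1.85 higher at day 7 than at day 1.

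At day 7 most contractile genes were lower than before culture, and most measured genes of DNA replication and mitosis and 16 of 27 genes of wounded and differentiating epidermis were higher. Of the 19 lists called, 0 stayed called with an estimated correlation (adjusted p = 0.179 for contractile, 0.19 for replication, 0.194 for mitosis and 0.225 for epidermal genes). Against pre-culture cells the largest rises included Prl2c2 (8.17 ± 0.366, adjusted p = 3.29e-10, n = 4 per group), one of the proliferin hormones, the wound keratin Krt6b (8.05 ± 0.192, adjusted p = 1.11e-12) and the epidermal protease Klk8 (7.68 ± 0.162, adjusted p = 4.54e-13). The median rise of Prl2c2, Prl2c3 and Prl2c4 was 7.92. The largest falls were in the secreted lectin Chil1 (-8.01 ± 0.207, adjusted p = 2.43e-12), in Igfbp5 (-7.96 ± 0.135, adjusted p = 6.77e-14) and in the smooth muscle myosin Myh11 (-7.17 ± 0.273, adjusted p = 7.92e-11). The iron-sequestering protein gene Lcn2 fell (-6.59 ± 0.151, adjusted p = 8.11e-13).

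The fit called 8394 genes, 4517 higher and 3877 lower at day 7 than before culture, of which 4003 changed at least 2-fold (2146 upward, 1857 downward). Under median centring 64.1% of the called genes were higher, against 53.8%, and of those that changed at least 2-fold 67.5% against 53.6%. For the day 1 comparison that share was 76.2% under median centring against 53.2%. Within beadchip 1 alone 7466 genes were called and within beadchip 2 alone 7407, and with the beadchip as a block 8495.

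Of the 22 contractile genes 19 were lower at day 7 and 0 higher (20 and 0 adjusted over the list alone). Camera gave the list adjusted p = 4.52e-11, and adjusted p = 0.179 with an estimated correlation. Acta2 fell (-2.83 ± 0.390, adjusted p = 2.53e-05) and Mylk, the kinase that triggers smooth muscle contraction, (-6.56 ± 0.164, adjusted p = 1.65e-12). Epidermal differentiation and wound keratinocyte genes rose in 16 of 27 cases and fell in 2 (16 and 3 adjusted over the list alone). The list test gave adjusted p = 0.000212, and adjusted p = 0.225 with an estimated correlation. Examples were Krt6a (6.07 ± 0.303, adjusted p = 9.37e-10) and the cornified envelope gene Sprr1b (5.99 ± 0.334, adjusted p = 2.69e-09). Mitosis genes now rose in 19 of 24 cases and fell in none (19 and 0 adjusted over the list alone, camera adjusted p = 3.39e-06, adjusted p = 0.194 with an estimated correlation), with Birc5 up by 4.34 ± 0.315 (adjusted p = 3.68e-08) and the mitotic kinase Aurka by 3.89 ± 0.275 (adjusted p = 2.87e-08). DNA replication genes were higher in 25 of 28 cases (25 adjusted over the list alone). As a list they had adjusted p = 1.46e-09, and adjusted p = 0.19 with an estimated correlation. Cholesterol synthesis genes rose in 16 of 17 cases and fell in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 1.83e-07, adjusted p = 0.179 with an estimated correlation), for example the cyclase Lss (3.65 ± 0.168, adjusted p = 4.16e-10). Ribosome biogenesis genes rose in 14 of 23 cases and fell in 1 (14 and 1 adjusted over the list alone). Camera put the list at adjusted p = 0.000322, and adjusted p = 0.194 with an estimated correlation.

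Most stress and stromal lists were again lower at day 7, but the pericyte list (4 of 11 fell, 2 rose, adjusted p = 0.131), the adipocyte list (4 of 14 fell, 1 rose, adjusted p = 0.222) and the oxidative stress NRF2 list (5 of 20 rose, 8 fell, adjusted p = 0.588) were not called. Of 26 immediate-early and heat shock genes 24 fell and 0 rose (25 and 0 adjusted over the list alone). Camera gave the list adjusted p = 2.94e-12, and adjusted p = 0.0511 with an estimated correlation. Hypoxia and glycolysis genes fell in 16 of 25 cases and rose in 2 (16 and 3 adjusted over the list alone). The list test gave adjusted p = 4.68e-05, and adjusted p = 0.179 with an estimated correlation. Interferon response genes fell in 18 of 22 cases (18 adjusted over the list alone). As a list they had adjusted p = 2.91e-09, and adjusted p = 0.19 with an estimated correlation. Fibroblast and feeder cell genes fell in 19 of 25 cases and rose in 1 (21 and 2 adjusted over the list alone, camera adjusted p = 3.02e-07, adjusted p = 0.179 with an estimated correlation), and Col1a1 stood at 7.26 at day 7, next to the array median of 7.32. Immune cell genes (13 of 22 fell, 1 rose, adjusted p = 0.00358, and adjusted p = 0.368 with an estimated correlation) and endothelial genes (9 of 18 fell, 1 rose, adjusted p = 0.0151, and adjusted p = 0.19 with an estimated correlation) were called lower, the latter not among genes above the median by mean (0.105). The endothelial gene Egfl7 went the other way (2.87 ± 0.227, adjusted p = 8.72e-08).

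Among the lists tied to lineage and signalling, luminal epithelial genes were lower at day 7 (13 of 24 fell, 2 rose, camera adjusted p = 0.00196, adjusted p = 0.179 with an estimated correlation), with Krt18 down (-2.19 ± 0.161, adjusted p = 4.27e-08) and Krt8 (-1.10 ± 0.269, adjusted p = 0.00354). The glycoprotein gene Ly6d rose by 4.46 ± 0.314 (adjusted p = 2.74e-08). Milk protein genes were lower (7 of 16 fell, 0 rose, camera adjusted p = 0.0305, adjusted p = 0.179 with an estimated correlation), with Csn3, a casein, down (-3.11 ± 0.312, adjusted p = 1.04e-06). Basement membrane genes (12 of 18 fell, 1 rose, adjusted p = 5.29e-05, and adjusted p = 0.179 with an estimated correlation), epithelial-mesenchymal transition genes (10 of 21 fell, 3 rose, adjusted p = 0.0103, and adjusted p = 0.295 with an estimated correlation) and YAP and TEAD targets (9 of 20 fell, 5 rose, adjusted p = 0.00737, and adjusted p = 0.273 with an estimated correlation) were also lower. The mesenchymal filament gene Vim fell (-3.30 ± 0.214, adjusted p = 1.16e-08) and the secreted YAP target Ccn2 (-3.59 ± 0.303, adjusted p = 1.73e-07). Wnt target genes were lower as a list (8 of 15 fell, 2 rose, camera adjusted p = 0.0245, adjusted p = 0.19 with an estimated correlation). The stem cell receptor Lgr5 fell (-2.09 ± 0.164, adjusted p = 8.29e-08) and the feedback inhibitor Nkd1 (-4.51 ± 0.121, adjusted p = 3.35e-12), while Axin2, another feedback gene of the pathway, rose by 0.48 ± 0.118 (adjusted p = 0.00346).

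Of 8 EGF family ligand genes 4 rose and 0 fell (4 and 0 adjusted over the list alone), led by Epgn (5.41 ± 0.192, adjusted p = 4.1e-11) and Hbegf (2.76 ± 0.136, adjusted p = 8.46e-10). The list's call at day 7 (camera adjusted p = 0.0449, adjusted p = 0.19 with an estimated correlation) ended without replicate 4 of pre-culture (adjusted p = 0.0538), without replicate 1 of day 7 (0.0511) and without replicate 4 of day 7 (0.0718), and within beadchip 1 (0.132). It also ended with the beadchip as a block (0.0534), under median centring (0.0592) and without experiment 1 (0.0598). Basal identity genes were not called as a list (10 of 24 rose, 6 fell, adjusted p = 0.805, mean -0.14, median 0.05), but Krt5 rose by 1.70 ± 0.171 (adjusted p = 1.07e-06) and the basal keratin Krt15 fell (-4.37 ± 0.248, adjusted p = 3.22e-09). Wnt ligand and receptor genes (5 of 32 rose, 14 fell, adjusted p = 0.0584, and 0.0495 with the replicate number as a block), Notch pathway genes (7 of 22 rose, 6 fell, adjusted p = 0.805), proposed mammary stem cell genes (6 of 22 rose, 8 fell, adjusted p = 0.195), integrin and focal adhesion genes (5 of 23 rose, 12 fell, adjusted p = 0.0584) and p53 target genes (11 of 22 rose, 8 fell, adjusted p = 0.876, mean -0.21, median 0.17) were not called at day 7. The integrin list was called lower within beadchip 1 (0.00355), with array weights (0.0387), without replicate 2 of pre-culture (0.0466), without replicate 1 (0.0239) or 4 (0.0443) of day 7 and without experiment 1 (0.029). Its adjusted p was 0.524 for camera with an estimated correlation and 0.00157 for fry, which compares with no other genes. The Wnt ligand list was also called within beadchip 1 (0.0116), with array weights (0.0408), without replicate 2 of pre-culture (0.0322) and without replicate 1 of day 7 (0.0433). For this list camera with an estimated correlation gave 0.368 and fry 1.85e-05. Within these lists single genes moved far. Wnt4 rose by 4.54 ± 0.124 (adjusted p = 3.91e-12) and its receptor family member Fzd7 fell (-5.50 ± 0.175, adjusted p = 1.47e-11), the Notch effector Hey1 fell (-6.03 ± 0.0864, adjusted p = 1.06e-14) and the Notch feedback gene Nrarp rose by 3.69 ± 0.104 (adjusted p = 5.16e-12). Sox10, a transcription factor of neural crest and mammary stem cells, fell (-5.83 ± 0.0730, adjusted p = 7.01e-15).

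**Figure D3:**
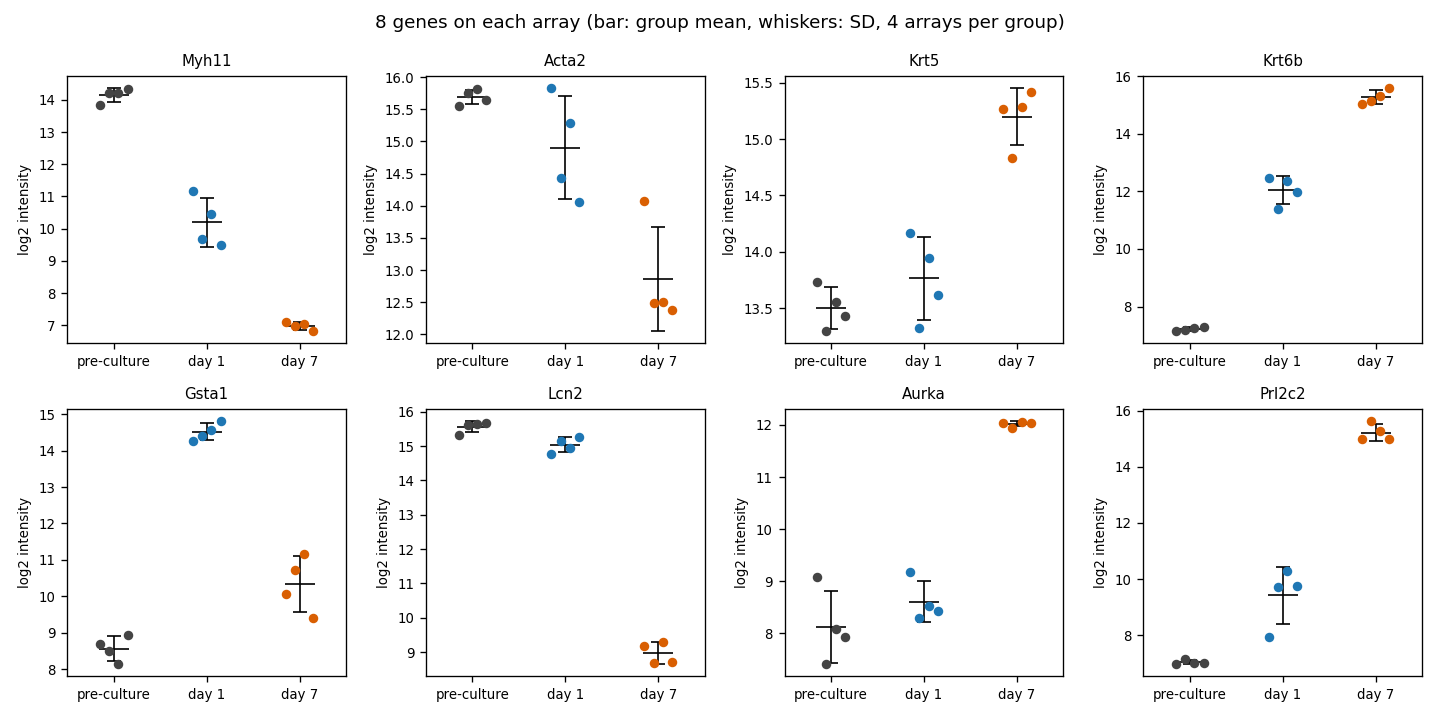
Log2 intensity of 8 genes on each array, by group (points: arrays, bar: group mean, whiskers: SD, n = 4). Myh11 fell in steps to 6.98 at day 7, Lcn2 stood at 15.04 at day 1 and at 8.97 at day 7, Gsta1 was highest at day 1 (14.51), and Krt6b and Prl2c2 reached 15.27 and 15.21 at day 7.

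Between day 1 and day 7, in the interval over which the labelled stem cell frequency went from 1 in 30 to 1 in 70, most mitosis and cholesterol synthesis genes and 15 of 27 epidermal genes rose, and 15 of 20 NRF2 targets fell. Only the NRF2 list stayed called with an estimated correlation (adjusted p = 0.0189), and the mitosis (0.167), cholesterol (0.089) and epidermal lists (0.213) did not. The largest rises included the receptor gene Klra4 (5.80 ± 0.0802, adjusted p = 2.63e-14, n = 4 per group, with 2 of its 4 probes called), Prl2c2 (5.79 ± 0.366, adjusted p = 9.46e-08), Plac8 (5.68 ± 0.269, adjusted p = 6.93e-09) and the stress keratin Krt16 (5.63 ± 0.245, adjusted p = 4.27e-09). Prl2c3 and Prl2c4 rose by no less than 5.72. The largest falls were in Lcn2 (-6.07 ± 0.151, adjusted p = 2.01e-11), Slc7a11 (-4.47 ± 0.247, adjusted p = 2.63e-08) and Gsta2 (-4.46 ± 0.285, adjusted p = 1.06e-07). The fit called 4803 genes, 2105 higher and 2698 lower at day 7, and 1127 changed at least 2-fold (616 upward, 511 downward). Of the latter 44.3% were upward under median centring against 54.7% as normalized. Within beadchip 1 alone 4619 genes were called, within beadchip 2 alone 3111, and with the beadchip as a block 4990.

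Of 24 mitosis genes 19 rose and 0 fell (19 and 0 adjusted over the list alone, camera adjusted p = 3.63e-13, adjusted p = 0.167 with an estimated correlation), with the centromere histone Cenpa up by 4.31 ± 0.371 (adjusted p = 1.65e-06) and Aurka by 3.41 ± 0.275 (adjusted p = 9.05e-07). Of 17 cholesterol synthesis genes 15 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 4.35e-13, adjusted p = 0.089 with an estimated correlation), for example Stard4, a sterol carrier (2.02 ± 0.157, adjusted p = 6.24e-07). Epidermal genes rose in 15 of 27 cases and fell in 1 (16 and 1 adjusted over the list alone). Camera put the list at adjusted p = 4.93e-08, and adjusted p = 0.213 with an estimated correlation. DNA replication genes (15 of 28 rose, 2 fell, adjusted p = 4.86e-06, and adjusted p = 0.418 with an estimated correlation) and hypoxia and glycolysis genes (14 of 25 rose, 1 fell, adjusted p = 3.19e-05, and adjusted p = 0.178 with an estimated correlation) were also higher. The p53 target and cell cycle inhibitor list (8 of 22 rose, 5 fell, adjusted p = 0.0431, and adjusted p = 0.418 with an estimated correlation) lost its call without replicate 1 or 3 of day 1 (0.0933 and 0.0579), without replicates 1, 2 or 3 of day 7 (0.0763, 0.0566 and 0.0622) and within beadchip 2 (0.192). It was also lost under median centring (0.231), among genes above the median by mean (0.113) and without experiment 1 (0.101).

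NRF2 targets fell in 15 of 20 cases and rose in 1 (15 and 1 adjusted over the list alone), the single list between the cultures whose call held with an estimated correlation (camera adjusted p = 2.52e-09, and 0.0189 with an estimated correlation). Gclm fell (-2.61 ± 0.119, adjusted p = 5.98e-09) and the heme-degrading Hmox1 (-2.63 ± 0.190, adjusted p = 3.11e-07). Contractile genes fell further in 12 of 22 cases (14 fell and 1 rose adjusted over the list alone). Camera gave the list adjusted p = 4.7e-06, and adjusted p = 0.388 with an estimated correlation. Acta2 was lower (-2.04 ± 0.390, adjusted p = 0.00131), and within beadchip 2 its difference of -1.44 was not called (adjusted p = 0.106). Ribosome biogenesis genes (12 of 23 fell, 0 rose, adjusted p = 6.82e-05, and adjusted p = 0.261 with an estimated correlation), immediate-early genes (11 of 26 fell, 1 rose, adjusted p = 0.00147, and adjusted p = 0.261 with an estimated correlation), Wnt targets (5 of 15 fell, 0 rose, adjusted p = 0.00802, and adjusted p = 0.213 with an estimated correlation) and YAP and TEAD targets (8 of 20 fell, 1 rose, adjusted p = 0.00719, and adjusted p = 0.418 with an estimated correlation) were lower. Their calls ended within beadchip 1 for immediate-early genes (0.0866) and within beadchip 2 for Wnt targets (0.0743, and 0.0648 among genes above the median by mean) and YAP and TEAD targets (0.168). Myc itself fell (-1.32 ± 0.147, adjusted p = 1.57e-05).

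The changes of day 1 and day 7 against pre-culture were largely shared. Across the 19057 genes, which are not independent replicates, their log2 fold changes correlated at r = 0.848, where unchanged groups simulated against the same pre-culture arrays gave 0.498, and their covariance was 0.708 against a simulated 0.00838, a difference of 0.699. With 2 of the pre-culture arrays used for each comparison, r lay between 0.801 and 0.849 and the covariance between 0.683 and 0.711. Both comparisons called 3418 genes higher (0 in the simulation, 1012 for independent lists) and 2904 lower (0 and 696.2), and 212 were called in opposite directions. The simulated 0 comes from unchanged groups, in which few genes are called at all.

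Day 1, the group with the highest labelled stem cell frequency, stood apart for a small set of genes. At least 2-fold above both other groups were 89 genes, where independent lists would give 46.47 and separate sets of 2 day 1 arrays gave 85 to 94. The simulation gave 0, but its groups are unchanged and yield few calls, so it is no measure for groups that differ. At least 2-fold below both were 113 genes (0 in the simulation, 49.26 for independent lists, 104 to 109 with sets of 2). Both independent counts take in all 19057 genes, although nearly all 2-fold changes lay in genes above the median by mean. With only those 9528 genes, 1732 rose at least 2-fold at day 1 and 510 fell at least 2-fold from day 1 to day 7. That setting still held 89 genes highest and 119 lowest at day 1. The independent counts are therefore too low a measure, and no excess is read from them. The first set was headed by Gsta2, Gsta1, Slc7a11, the actin-bundling gene Avil (3.07 ± 0.127 against pre-culture, adjusted p = 3.46e-10, n = 4 per group) and the drug exporter Abcc4 (3.11 ± 0.169, adjusted p = 3.35e-09), ordered by the smaller of the changes against the other groups. The second was headed by Plac8 (-3.66 ± 0.269, adjusted p = 6e-08), the mitochondrial gene Mgarp (-4.22 ± 0.308, adjusted p = 5.46e-08), the lysosomal protease Ctsh (-3.10 ± 0.191, adjusted p = 1.07e-08) and Krt16 (-2.32 ± 0.245, adjusted p = 2.17e-06), and held the histone genes H4c18 (-2.50 ± 0.127, adjusted p = 1.83e-09) and H4c6 (-2.38 ± 0.138, adjusted p = 6.01e-09), whose coding sequences are near-identical, so that probes may not tell them apart. Under median centring the sets held 199 and 69 genes, and with the mean of each gene's probes the second held 72.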

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

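The tests of the Prl2c genes, of stromal cells, of quantile normalization and of culture length were chosen only after the results were seen, as were the genes they concern, while the beadchip test and the counts over other splits of the arrays were set before their results.

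Prl2c2, Prl2c3 and Prl2c4, which encode proliferins, rose from day 1 to day 7 by 5.72 to 5.79, and fibroblast feeder cells that escaped the second sort are a candidate source. The fixed list of 25 fibroblast and feeder cell genes speaks against that: its median change over the same interval was -0.158 (SD of members 0.935), and Col1a1, Col1a2 and Col3a1 stood at 7.26, 7.23 and 7.13 at day 7, around the array median of 7.32. The 3 rises differed by at most 0.0725, under the standard error of a difference of 0.543. That error treats the genes as read on separate arrays, although they share the same arrays. The check therefore cannot tell signal shared between near-identical family members from genes that rose together. Which of them rose is not known. The rise held under each scaling, with a median of 5.94 after normexp correction and 5.66 under median centring. Whether the basal cells themselves switched the family on in culture remains an untested hypothesis.

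Fibroblast and feeder cell genes were lower in both cultures than before culture, and stromal cells carried along by the first sort, which the labels put at 95% purity, are a candidate source. Over the pre-culture arrays Col1a1, Col1a2 and Col3a1 varied together (mean pairwise r = 0.946, with a 95th percentile of 0.628 for random genes of like expression), and replicate 4 exceeded the mean of the others by 1.71, 1.19 and 1.96. Dcn and Mmp2 followed them (mean r = 0.586, 95th percentile 0.551), but replicate 4 exceeded the others by only 0.256 and 0.333, so for these genes a fall within the basal cells stays open beside stromal cells. Quantile normalization is argued against as the whole cause, since the list's mean change at day 1 was -1.04 ± 0.145 (SE) under median centring, next to -1.41 ± 0.155. The whole list had a mean pairwise r of 0.414, above all 2000 random lists (median -0.00884), but the tests of its parts were chosen among several after the values of its members were seen and rest largely on 1 of 4 arrays.

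Day 7 arrays of replicates 1 and 4, which shared beadchip 2, lay apart from replicates 2 and 3 on the third principal component (28.7 and 9.80 against -14.6 and -17.9). An effect of the beadchip common to day 7 and day 1 is argued against: their beadchip differences correlated at -0.084 across 9528 genes. The correlation of day 7 with pre-culture was 0.0699 and cannot decide. In pre-culture replicates 1 and 4 were on beadchip 1, where day 7 had replicates 2 and 3. Effects of the pools and of the beadchip would therefore work against each other in that value. The day 7 samples were collected 7, 8, 11 and 8 days after the sort of the same number, a match by order in the titles in which the 11 days may be a mismatch, and the slope on those days correlated at 0.245 with the day 1 to day 7 change. That value lies between the bounds set for and against culture length, which therefore stays open with 4 arrays. Differences between the pools of mice may also contribute and could not be told apart from either.

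An array far from the other 3 of its group was found in 17 of 477 groups of values tested (130 genes, 28 lists and the raw median, in 3 groups each), where chance gives about 1 in 20, or 23.8. Of the 17, 7 were in replicate 1 of day 1 and 5 in replicate 1 of day 7. In replicate 1 of day 1 the log2 values were 9.488 for Fbxo32 (others 8.949 to 9.039), 10.06 for Wnt4 (9.569 to 9.63), 7.526 for Prl2c4 (9.34 to 9.664), 10.11 for Chil1 (11.11 to 11.22), 11.9 for Mylk (11.06 to 11.15), 9.474 for Plk1 (8.291 to 8.486) and 10.24 for the mean of the immediate-early and heat shock list (10.42 to 10.44). In replicate 1 of day 7 they were 9.355 for Actg2 (others 7.998 to 8.046), 14.08 for Acta2 (12.38 to 12.5), 13.16 for Cdc20 (12.69 to 12.74), 8.005 for Myl9 (7.342 to 7.403) and 9.946 for the mean of the contractile list (9.514 to 9.585). The rest were Gsta2 in pre-culture replicate 4 (8.179, others 7.472 to 7.575), Srxn1 in pre-culture replicate 2 (12.41, others 11.74 to 11.83), the EGF ligand list in pre-culture replicate 3 (8.086, others 7.967 to 7.982), Fas in day 7 replicate 4 (7.99, others 8.622 to 8.707) and Nr1d1 in day 7 replicate 3 (7.267, others 7.179 to 7.186).

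For 9 of the 130 genes the change against pre-culture had opposite signs at day 1 and day 7, with both changes and the difference between the cultures called by limma. Over all 19057 genes 212 had both changes called with opposite signs. The 130 include genes named because they were extreme at day 1, such as Slc7a11, Plac8 and Krt16, so the 9 partly restate that choice. Day 7 exceeded day 1 by 5.627 for Krt16, 5.683 for Plac8, 3.268 for Tgfbi and 1.801 for Pdk1. The difference was -4.474 for Slc7a11, -2.607 for Gclm, -3.196 for Id4, -2.707 for Srxn1 and -3.19 for Cbr3.

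Of 10395 probes paired with no gene or with several, 590 changed at least 2-fold between pre-culture and day 1, 676 between pre-culture and day 7 and 174 between the cultures. These are 5.68%, 6.5% and 1.67% of them, against 13.5%, 16.6% and 4.3% of the named probes.

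The gene counts were set beside those of other splits of the 8 arrays of each comparison, 35 in number with the real one. The real split gave the most genes each time. Splits that mix the groups put the group difference into the spread, so few genes can be called in them. Their low counts therefore do not exclude chance. For day 1 against pre-culture 1 split gave 7692 genes (highest other 0) and 1 gave 3257 changed at least 2-fold (highest other 0). For day 7 against pre-culture 1 split gave 8394 (highest other 1) and 1 gave 4003 (highest other 1), and for day 7 against day 1 the numbers were 1 split with 4803 (highest other 2) and 1 with 1127 (highest other 0). Among the 8 splits that part the pairs as the real one does, no other gave a gene, though 1 of 8 is the least that they can show. For the lists, 3 of 35 splits gave at least the 16 of day 1 against pre-culture (highest other 16, and 2 of the 8 paired splits), 2 of 35 the 19 of day 7 against pre-culture (highest other 19, and 18 among the paired splits) and 1 of 35 the 12 of day 7 against day 1 (highest other 11, also among the paired splits, with 11 to 13 when 1 array was left out). By that count alone chance is not excluded for the lists against pre-culture, and for the cultures the margin is 1 list. The 16 splits that keep 3 of the 4 arrays of a group together leave part of the group difference in place, however, and all the splits that reached the real count against pre-culture were among them (medians of 14, 16 and 9 lists in the order above). The 18 splits that divide each group evenly, looked at only after these counts were seen, gave at most 6, 5 and 9 lists, with medians of 2, 1.5 and 2, and are too few for a share under 0.05. Splits by beadchip gave 3, 1 and 2 lists and 0 genes. Of 100 regroupings of all 12 arrays 1 gave 89 genes highest and 1 gave 113 lowest at day 1 (highest other 0 each). Regroupings that mix the groups put their differences into the spread and leave few genes to call, so these counts do not exclude chance. A correlation as large as 0.8479 came from 24 of 100 (highest other 0.9937), but regroupings that mix the groups carry real differences into the shared arrays, so this value says nothing about chance. The comparison with simulated unchanged groups (r = 0.498, covariance 0.00838 against 0.7076) and with separate pre-culture arrays (r = 0.8006 to 0.8486) does not rest on it.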

How the results depend on the processing

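The setting that leaves out experiment 1 was chosen only after the data were seen, because 12 of the 17 cases of an array standing apart were in its cultures. The others were set before. Of 427 results on named genes 383 kept their direction and their side of the threshold in all settings run, and over 11521 values 77 lost and 53 gained a call with 0 reversed. Of 84 list results 18 did so, with 71 losses, 40 gains and 2 reversals in 2346 values. Of the 71 losses, 44 came from camera with an estimated correlation, which left 2 lists called at day 1, 0 at day 7 and 1 between the cultures. With fry 26 lists were called at day 1, and the Notch list had a mean of -0.1051 at day 1 and -0.001388 at day 7, opposite to the direction given by camera, which compares the list with the other genes.

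With the replicate number as a block (paired) 7636, 8296 and 4763 genes were called for day 1 and day 7 against pre-culture and for day 7 against day 1, and on named genes it lost 1 call (Krt14) and added 4, among them Cenpa at day 1 (adjusted p = 0.0419). Within beadchip 1, with 2 arrays per group, 137 genes were highest at day 1 and the correlation of the day 1 and day 7 changes was 0.8099. Within beadchip 2, with as few, 3111 genes were called between the cultures and the correlation was 0.8644. Median centring gave 199 genes highest and 69 lowest at day 1 and a correlation of 0.8396. The mean of a gene's probes gave 741 genes changed at least 2-fold between the cultures and 72 lowest at day 1. Every probe, counted as probes and so over more features, gave 14043 and 5299 at least 2-fold at day 1, 15329 and 6481 at day 7, and 7804 between the cultures. Array weights gave a correlation of 0.8407 and leaving out experiment 1 gave 0.8356. The causes of these shifts were not tested.

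Leaving out 1 array at a time gave 7211 to 7902, 8075 to 8346 and 4128 to 5263 genes for the 3 comparisons in the order above, 3208 to 3351, 3945 to 4095 and 1063 to 1250 at least 2-fold, 15 to 17, 18 to 21 and 11 to 13 lists, 82 to 112 genes highest and 99 to 135 lowest at day 1, and a correlation of 0.8354 to 0.856. Without experiment 1 the counts were 7548, 8226 and 5101, of which 7214, 7835 and 4403 were the same genes.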

Other observations

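The tests of replication against mitosis, of NRF2 targets among the genes highest at day 1 and of the histone genes were chosen only after the results were seen, as were the clock genes and the paired form of the first test.

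Some genes of the circadian clock were lower in culture. They were not a fixed list and were not tested against other genes, in a comparison that called 7692 of 19057. Of 16 measured clock genes 10 fell at day 1 and 0 rose, and at day 7 12 fell and 0 rose. The clock output transcription factor Dbp fell at day 1 (-5.68 ± 0.154, adjusted p = 8.9e-12, n = 4 per group), the repressor Nr1d1 (-4.13 ± 0.122, adjusted p = 2.17e-11) and Per2 (-2.05 ± 0.155, adjusted p = 7.45e-08). The activators Arntl (-0.22 ± 0.104, adjusted p = 0.113) and Clock (-0.10 ± 0.105, adjusted p = 0.557) were not called at day 1. Neither were Hlf (-0.12 ± 0.0838, adjusted p = 0.329), Per3 (-0.12 ± 0.0707, adjusted p = 0.219), Cry1 (-0.06 ± 0.0914, adjusted p = 0.696) and Npas2 (-0.12 ± 0.106, adjusted p = 0.467). These last genes stood at 7.29, 7.46, 6.98 and 7.22 before culture, near the array median of 7.32, so a fall in them could hardly show. Under median centring 10 fell and 2 rose at day 1, and 10 fell and 0 rose at day 7. Times of day are not used here, so a difference in sampling time between the groups was not tested.

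DNA replication genes were higher at day 1 while mitosis genes as a list were not, and the difference of the list means was looked at on each array for that reason, so its test restates what prompted it. The mean of the replication list minus that of the mitosis list was 1.16 higher at day 1 than before culture (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 arrays can give). It was higher at day 1 in all 4 experiments. The permutation test ignores that the groups share pools, and a paired one cannot decide here, since its exact p of 0.125 is the smallest that 4 pairs can give. The difference of the list means ranged from 0.042 to 0.513 in pre-culture arrays, from 1.36 to 1.67 at day 1 and from 0.245 to 0.430 at day 7, so that day 1 overlapped neither other group. Whether replication genes rise ahead of mitosis genes after plating was not tested on other data. Between day 1 and day 7 the difference went down, at -1.19 (exact permutation p = 0.0286, paired 0.125), and day 7 and pre-culture differed by -0.0334 (exact permutation p = 0.8286, paired 0.75).

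Replication-dependent histone genes went the other way. Of 55 histone cluster genes, looked at because H4c18 and H4c6 were among the genes lowest at day 1, 43 fell and 1 rose at day 1, with a median of -1.13, below all 10000 random lists matched on mean expression (under median centring 29 fell and 4 rose, median -0.769). Between day 1 and day 7, 42 rose and 3 fell, with a median of 1.38 (1.23 under median centring). At day 7 against pre-culture 19 rose and 19 fell, and the median of -0.0775 became 0.194 under median centring. That median joins unlike genes. H1f2 and H2bc11 fell at day 1 (-3.00 and -4.23) and were still lower at day 7 (-3.71 and -2.82). H2ac15 and H2ac21 fell less at day 1 (-1.17 and -1.27) and were higher at day 7 (1.71 and 1.70). Some, such as H2ac20 (15.91) and H2ac24 (15.93), stood near the top of the scale at day 7, where rises can be compressed. Histone gene copies are near-identical, so these are not 55 independent measurements. The cause of the fall was not tested.

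The genes highest at day 1 included several NRF2 targets, which restates the rise and fall of that list and is no separate evidence for a transient response. Of 20 NRF2 targets 6 were among the 89 genes highest at day 1, against an expected 0.0934 (Fisher's exact odds ratio 97.4, adjusted p = 1.8e-08 over 56 tests of 28 lists in both sets). Among the 113 genes lowest at day 1 were 3 of 25 hypoxia genes and 3 of 27 epidermal genes (adjusted p = 0.00999 each), against 0.148 and 0.16 expected. Fisher's test treats genes as independent, which they are not.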
